A study of Homo sapiens with 4 samples.

How the data were processed

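Gene count tables of human 143B osteosarcoma cells were used, 1 for each of 4 libraries. Cells had been transfected for 48 h with ALKBH5 siRNA or scrambled siRNA, and per the labels the libraries were made with a stranded messenger RNA kit and sequenced as single reads of 50 bases. The deposited values are whole-number counts of reads per gene symbol, not normalised. The submitters' processing notes name CASAVA 1.8.2, TopHat2, SAMtools, HTSeq and the genome build hg19. The roles and settings of these tools, the annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping antisense genes may have been mixed, and genes with near-identical copies are named as uncertain.

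Each table held 23228 genes and 5 summary categories that name no gene, which were left out of library sizes and tests. Those categories made up 47.5% and 49.1% of all entries in knockdown replicates 1 and 2 and 47.8% and 50.5% in scrambled replicates 1 and 2, mostly alignments that were not unique (37.9%, 40.8%, 39.3% and 42.0%). Gene counts totalled 15617725, 20213225, 25860501 and 20489687 in the same order. The 10 most abundant genes took 4.40% to 4.57% of the counts. Libraries of a group differed beyond sampling noise (chi-square per degree of freedom 28.5 between the knockdown and 42.2 between the scrambled libraries) and were counted as separate. The first principal component of log2 CPM held 71.1% of the variance and the second 19.3%. The labels give no batch.

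Groups were taken from the sample titles. Genes were filtered with filterByExpr, which kept 13644, and scaled with TMM factors of 0.971 to 1.01. The comparison was an edgeR quasi-likelihood F test with robust dispersion and no block (edgeR 4.0.16, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation was 17.1%. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM values use TMM-scaled library sizes and are given as mean ± SD.

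The gene lists were m6A machinery, histone ubiquitination enzymes, DNA replication, double strand break and crosslink repair, mitosis, p53 targets, apoptosis regulators, interferon-stimulated genes, NF-kB and inflammatory genes, the integrated stress and unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, YAP/TEAD targets, extracellular matrix and mesenchymal genes, osteoblast genes, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded transcripts, replication-dependent histones, immediate-early genes, and epithelial, leukocyte and endothelial markers. None of the mitochondrially encoded transcripts was matched in the tables used here, so that list has 0 genes and no result. These 23 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Another 2 lists, SRF/MRTF targets and mitochondrial ribosomal proteins, were added after the results were seen. Lists were tested with camera at a preset correlation of 0.01 (limma 3.58.1), and again with an estimated correlation and with fry.

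ALKBH5, USP22 and RNF40 were always named, the latter pair because the study is known to have followed them. The 12 largest rises and 12 largest falls were then named among genes with an adjusted p under 0.05, a mean of at least 5 CPM and libraries that did not overlap between groups. For each list up to 4 members with the smallest p past the threshold were eligible, or 2 where none passed. The value of 1 eligible list member is not reported here.

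The steps were tested on simulated counts with the means and sizes of these libraries. Of the genes changed in the simulation, 1.49% were recovered at 1.5-fold, 40.3% at 2-fold and 93.9% at 4-fold, and 5 of 13444 unchanged genes were called. The simulation changed 67, 67 and 66 genes at these folds, a far smaller share than the 20.2% of genes called in these data. Its adjusted threshold was therefore stricter, and its recovery rates do not carry over to these data. Small changes may still be missed with 2 libraries per group. In the simulated list test, where each gene was drawn independently, 2 of 200 random lists fell below 0.05. Correlations estimated for the lists fixed beforehand ran from -0.147 (leukocyte markers) to 0.837 (mitosis), so the simulation does not test the list results under such correlation. Planted 7-mers ranked first in 20 of 20 trials. They were given the shift of the lowest-scoring 7-mer of these data, on permuted values, so smaller shifts were not tested.

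Sequence content was taken from GENCODE release 29 transcripts. The files name hg19 and this reference is GRCh38, so it was used for transcript sequence only, and no coordinates are given. Symbols of 92.3% of the tested genes were matched to a coding transcript, and 91.5% had a 3′ UTR of at least 50 nt. All 7-mers found in at least 20 genes, 16379 in number, were compared over the 10331 genes with a mean of at least 5 CPM, after the trends of 3′ UTR length and GC content had been removed and log2 fold changes limited to 3 in size. The labels of the fold changes were permuted 100 times across genes. This part used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

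The alternatives were DESeq2 size factors in edgeR, library totals alone, no filter beyond 1 count, a minimum mean of 5 CPM, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, and a minimum log2 change of 1.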

Results

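Messenger RNA was sequenced from 143B cells, an established human osteosarcoma line, 48 h after transfection with siRNA against ALKBH5 or with scrambled siRNA. ALKBH5 is a demethylase that removes N6-methyladenosine (m6A) from RNA. Each group held 2 libraries. The counts assigned to genes came to 15617725 and 20213225 in the knockdown libraries and to 25860501 and 20489687 in the scrambled libraries. Log2 CPM values (counts scaled to library size) correlated across genes at 0.984 within either group and at 0.951 to 0.961 between groups, where genes are not independent replicates. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

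The comparison asked how gene expression in osteosarcoma cells changed when ALKBH5 was reduced. The targeted gene, ALKBH5, was at 21.9 and 21.4 CPM in the knockdown libraries and at 120 and 130 CPM in the scrambled libraries. Its mean was 21.6 ± 0.328 CPM against 125 ± 6.76 CPM (SD, n = 2 in each group, as for all means given here), which is 5.77-fold lower. USP22, a deubiquitinase of the SAGA complex that acts on histone H2B, fell almost as far, from 362 ± 2.98 to 63.0 ± 0.362 CPM. RNF40, a subunit of the ubiquitin ligase that acts on histone H2B, fell from 144 ± 3.19 to 101 ± 2.30 CPM. The log2 fold changes were -2.53 (SE 0.15, adjusted p = 0.000521) for ALKBH5, -2.52 (SE 0.15, adjusted p = 0.000521) for USP22 and -0.51 (SE 0.14, adjusted p = 0.0374) for RNF40. RNF40 no longer passed when any 1 library was left out. Its adjusted p was 0.177 and 0.129 without knockdown replicates 1 and 2, and 0.104 and 0.110 without scrambled replicates 1 and 2. The annotated 3′ UTR of USP22 held the 7-mer GAGATGG 5 times, and the coding sequences of RNF40 and ALKBH5 held it 4 times and 1 time. This 7-mer was picked by scanning 3′ UTRs against the fold changes of these same libraries.

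Of 13644 genes tested, 1374 were higher and 1384 were lower after knockdown at an adjusted p under 0.05, together 20.2%. The change was at least 2-fold for 706 of the higher and 619 of the lower genes. Both knockdown libraries lay beyond both scrambled libraries in 63.2% of the tested genes, where chance gives 33.3%. With 1 library left out, the fit has fewer libraries to estimate the spread and called fewer genes. The higher genes numbered 462 and 615 without knockdown replicates 1 and 2, and 498 and 831 without scrambled replicates 1 and 2. The lower genes numbered 379 and 543, and 578 and 792, in the same order. GAGATGG stood in the 3′ UTR of 35.5% of the lower genes (476 of 1340 with a usable 3′ UTR), 15.1% of the higher genes (197 of 1308) and 19.4% of the genes past neither threshold (1909 of 9839).

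Of 1173 genes eligible for the largest rises, 12 were named. NPPB, the precursor of B-type natriuretic peptide, rose from 0.375 ± 0.152 to 13.5 ± 9.68 CPM, a log2 change of 5.19, and differed widely between the knockdown libraries. RGS4, which limits G protein signalling, rose from 2.09 ± 0.563 to 39.8 ± 7.76 CPM (log2 4.24). LCP1, an actin-bundling protein, rose from 1.99 ± 0.115 to 32.5 ± 9.70 CPM (log2 4.03), and TAGLN, an actin-binding protein of smooth muscle, rose from 8.13 ± 2.02 to 117 ± 41.4 CPM (log2 3.84). NLRC5, an activator of MHC class I genes, rose from 3.02 ± 0.373 to 45.7 ± 16.4 CPM (log2 3.92). CD274, which encodes the immune checkpoint ligand PD-L1, rose from 10.6 ± 5.92 to 81.6 ± 8.44 CPM (log2 2.96). The angiotensin receptor gene AGTR1 (log2 3.45), IGFBP5 (3.42), NIPAL4 (3.28), C6orf141 (3.11), ZNF185 (3.11) and AGR2 (3.10) completed the 12. All 12 had adjusted p-values of 0.000521 to 0.0149. AGR2 lost its call without knockdown replicate 2 (adjusted p = 0.0648), without scrambled replicate 1 (0.0923) and without scrambled replicate 2 (0.0537). Single libraries moved several folds. Without knockdown replicate 1 the log2 change was 2.74 for AGTR1, 2.81 for IGFBP5 and 3.76 for AGR2, and without knockdown replicate 2 it was 4.16 for NPPB and 1.79 for AGR2. Without scrambled replicate 1 it was 4.42 for AGTR1 and 4.78 for IGFBP5, and without scrambled replicate 2 it was 2.77 for IGFBP5 and 3.67 for CD274.

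The 12 largest falls took in ALKBH5 and USP22 themselves. TXNL4A, a component of the U5 spliceosomal particle, fell from 66.3 ± 4.26 to 7.86 ± 0.482 CPM, a log2 change of -3.07. PTMA, which encodes prothymosin alpha, fell from 406 ± 41.7 to 72.6 ± 5.21 CPM (log2 -2.48), and CPS1, the carbamoyl phosphate synthetase of the urea cycle, fell from 74.4 ± 4.90 to 12.4 ± 0.350 CPM (log2 -2.59). SERPINF1, which encodes pigment epithelium-derived factor, fell from 22.2 ± 0.501 to 3.02 ± 1.21 CPM (log2 -2.86). C15orf38 had the lowest log2 change, -4.22, followed further up by WDR76 (-2.80), FAM115A (-2.61), TCTN2 (-2.59), HMGN5 (-2.54) and FLRT3 (-2.50). The adjusted p-values of the 12 were 0.000521 to 0.0160. FLRT3 lost its call without knockdown replicate 2 (adjusted p = 0.0831) and without scrambled replicate 1 (0.0722, log2 -1.54). The values of PTMA, FAM115A and C15orf38 are uncertain, since PTMA has processed pseudogenes, FAM115A has a close paralog and C15orf38 overlaps a readthrough gene. Of the 11 falls with a usable 3′ UTR, 7 held GAGATGG there, against 2 of the 12 largest rises. The 7-mer was picked from the same fold changes, so this difference is not independent of that choice.

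**Figure D1:**
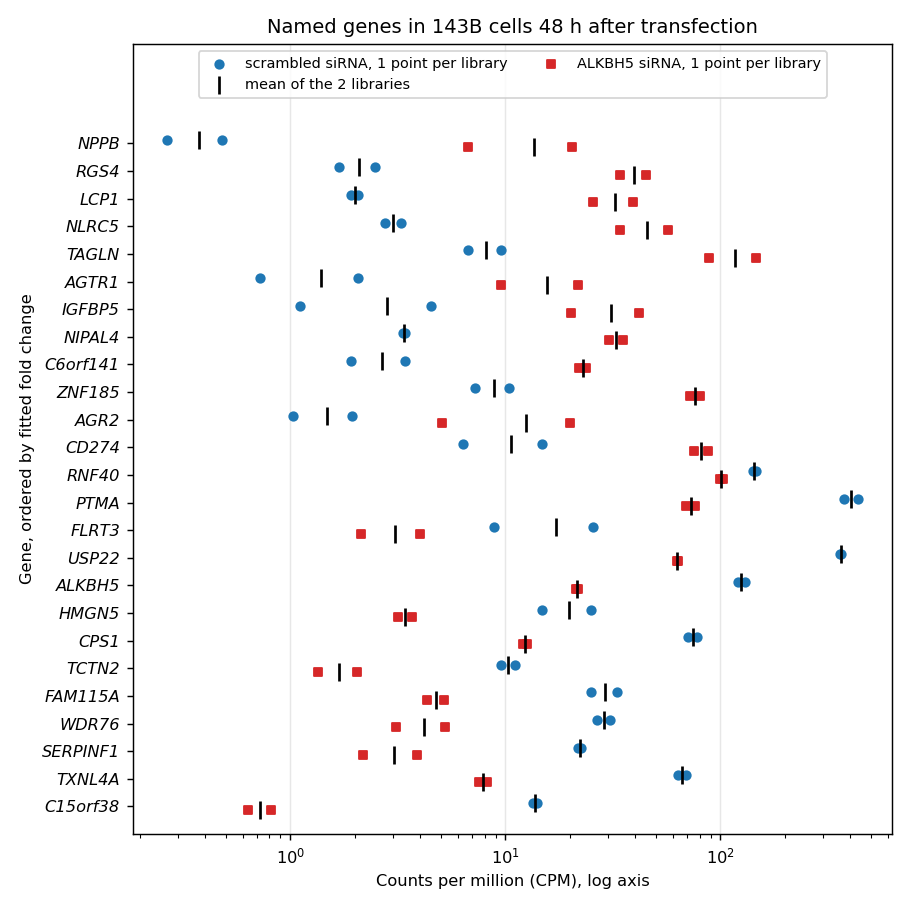
CPM (log axis) of ALKBH5, USP22, RNF40 and the 12 largest rises and 12 largest falls in 143B cells, with 1 point per library and a bar at the mean of the 2 libraries of each group. The knockdown and scrambled points do not overlap for any gene shown, which the rule for the rises and falls required. ALKBH5 and USP22 fell by 2.53 and 2.52 on the log2 scale.

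Among enzymes that add or remove ubiquitin on histones, 1 of 31 tested genes rose, 4 fell and 26 did not pass. PCGF5, a subunit of Polycomb repressive complex 1, rose from 26.3 ± 0.870 to 57.6 ± 2.44 CPM. BRCA1, a ubiquitin ligase of DNA repair, fell from 59.6 ± 8.97 to 29.8 ± 4.18 CPM, and the other falls were USP22, RNF40 and RNF20, the partner of RNF40 (log2 -0.49, adjusted p = 0.0493), which was named after its value was seen and lost its call when any 1 library was left out (0.126 to 0.229). Adjusted over the list alone, 1 rose and 3 fell, and the list did not pass for a common direction (median log2 change -0.11, camera adjusted p = 0.173). For change in either direction, fry gave an adjusted p of 0.0023, without comparing the list with other genes. USP22 and RNF40 are in this list because the study is known to have followed them, so their direction is not independent evidence. Among the other genes of the m6A machinery, 1 of 22 rose, 3 fell and 18 did not pass, and the counts adjusted over the list alone were also 1 and 3. ZC3H13, a subunit of the m6A writer complex, fell from 92.8 ± 17.9 to 36.6 ± 2.21 CPM (log2 -1.34), and METTL14, a core subunit of that writer, fell from 28.5 ± 1.17 to 16.7 ± 0.343 CPM (log2 -0.77). HNRNPC fell as well (log2 -0.64), and YTHDF3, an m6A reader, rose (log2 0.60). The list did not pass for a common direction (median log2 change -0.19, camera adjusted p = 0.136), while fry for either direction gave an adjusted p of 0.0155. METTL14, HNRNPC and YTHDF3 had adjusted p-values of 0.0236 to 0.0340 and lost their calls when any 1 of the 4 libraries was left out (0.0602 to 0.106, 0.0598 to 0.184 and 0.0555 to 0.168), and BRCA1 lost its call without knockdown replicate 2 or scrambled replicate 1 (highest adjusted p 0.0657).

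DNA replication genes fell together. Of 42 tested, 26 fell, none rose and 16 did not pass; adjusted over the list alone, 38 fell. The median gene was 2.06-fold lower (log2 -1.04), with medians of -1.38 to -0.54 over the 4 pairings of a knockdown with a scrambled library, lower in size against scrambled replicate 2. ORC1, a subunit of the origin recognition complex, fell from 49.0 ± 3.84 to 16.5 ± 0.686 CPM, and PRIM1, the catalytic primase subunit, fell from 41.7 ± 5.69 to 13.4 ± 0.686 CPM. GINS1, of the replicative helicase, had a log2 change of -1.82, and RRM1, the large subunit of ribonucleotide reductase, fell from 252 ± 44.1 to 104 ± 8.98 CPM. The list passed camera with a preset correlation (adjusted p = 1.12e-15) and not otherwise (adjusted p = 0.773 with an estimated correlation). GAGATGG stood in the 3′ UTR of 10 of the 42 genes, and the other 32 had the same median log2 change of -1.04.

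Genes of double strand break and crosslink repair were also lower. Of 40 tested, 18 fell, none rose and 22 did not pass, and adjusted over the list alone 22 fell. BLM, a RecQ helicase, fell from 29.2 ± 2.59 to 12.7 ± 0.164 CPM, RBBP8, which promotes end resection, from 67.5 ± 9.41 to 32.4 ± 1.33 CPM, and MRE11A, a nuclease of the MRN complex, from 52.3 ± 3.31 to 26.9 ± 1.40 CPM. The median log2 change was -0.67, with a camera adjusted p of 8.68e-07 (adjusted p = 0.773 with an estimated correlation).

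Mitotic genes did not move as a group. Of 40 tested, 1 rose, 3 fell and 36 did not pass, and none passed adjusted over the list alone. CDC25B, a phosphatase that activates mitotic cyclin-dependent kinase, rose from 69.2 ± 2.88 to 115 ± 14 CPM, while the spindle checkpoint gene MAD2L1 fell from 34.2 ± 11.5 to 15.7 ± 5.41 CPM. BUB1B and PRC1 fell too (log2 -0.53 and -0.63). The median log2 change was -0.25 and camera gave an adjusted p of 0.343. The direction rested on single libraries: the list test turned upward without scrambled replicate 1 (adjusted p = 0.0188) and passed downward without scrambled replicate 2 (5.69e-07). Each of the 4 named genes lost its call without scrambled replicate 1 and without knockdown replicate 1, with highest adjusted p-values of 0.104 for CDC25B, 0.196 for MAD2L1, 0.199 for BUB1B and 0.235 for PRC1, all but CDC25B also without knockdown replicate 2, and BUB1B also without scrambled replicate 2.

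Replication-dependent histone transcripts, by contrast with the replication enzymes, were higher. Of 18 tested, 10 rose, none fell and 8 did not pass; adjusted over the list alone, 13 rose. The median was 3.05-fold higher (log2 1.61). HIST1H2BK rose from 62.2 ± 7.64 to 157 ± 0.932 CPM, HIST2H2BE from 15.7 ± 8.11 to 61.6 ± 12.8 CPM and HIST1H2BD from 5.55 ± 0.545 to 25.6 ± 0.976 CPM. The log2 change of HIST2H2BE was 1.98 and moved to 2.63 without scrambled replicate 2. The list passed camera (adjusted p = 3.85e-06; adjusted p = 0.773 with an estimated correlation). These genes have near-identical copies, most lack long poly(A) tails, and most of the list was at low counts in messenger RNA libraries. Single values and the list median are therefore uncertain. The rise covers only the histone transcripts that these libraries captured, and total histone transcripts were not measured.

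Genes of the extracellular matrix and the mesenchymal state rose more often than they fell. Of 44 tested, 14 rose, 2 fell and 28 did not pass, and adjusted over the list alone 19 rose and 4 fell. TNC, which encodes tenascin C, rose from 117 ± 30.2 to 483 ± 89.8 CPM, and COL5A1, a chain of type V collagen, rose from 39.9 ± 15 to 234 ± 111 CPM, a log2 change of 2.55 that was 1.96 without knockdown replicate 1. ZEB2, a transcription factor of the mesenchymal state, went the other way, from 53.5 ± 9.02 to 14.5 ± 0.117 CPM. The median log2 change was 0.46 (camera adjusted p = 0.000306; adjusted p = 0.773 with an estimated correlation). Of 22 YAP/TEAD target genes, 9 rose, 1 fell and 12 did not pass, with 11 and 1 adjusted over the list alone. F3, which encodes tissue factor, rose from 24.9 ± 5.40 to 83.5 ± 19.0 CPM, RBMS3 from 6.90 ± 1.97 to 24.5 ± 0.220 CPM and MYOF, a membrane repair protein, from 781 ± 114 to 1616 ± 118 CPM. MYOF lost its call without either knockdown replicate or scrambled replicate 1 (highest adjusted p 0.0890). The median log2 change of the list was 0.47 (camera adjusted p = 0.00252; adjusted p = 0.773 with an estimated correlation).

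Immediate-early genes were higher in part. Of 21 tested, 6 rose, 1 fell and 14 did not pass, and adjusted over the list alone 8 rose and 1 fell. The transcription factor genes JUNB and KLF2 rose from 17.5 ± 0.579 to 55.1 ± 7.96 CPM and from 17.3 ± 3.23 to 59.8 ± 11.6 CPM, and the phosphatase gene DUSP1 rose from 26.4 ± 1.23 to 70.0 ± 12.1 CPM. The 1 fall was EGR1, named after its value was seen, at 25.8 ± 23.7 CPM in the scrambled and 5.90 ± 1.93 CPM in the knockdown libraries. Its log2 change was -2.14, and it lost its call without knockdown replicate 1 (adjusted p = 0.125), without knockdown replicate 2 (0.193) and without scrambled replicate 1 (0.334, log2 -0.62), while without scrambled replicate 2 the log2 change was -2.86. The camera adjusted p was 0.00447 (adjusted p = 0.773 with an estimated correlation), and it was 0.0634 without scrambled replicate 2.

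Stress and inflammatory lists held some changed genes without passing camera, which tests for a shift in a common direction. For change in either direction, fry gave adjusted p-values of 0.0328 (NF-kB), 0.0117 (interferon), 0.0023 (p53), 0.0328 (apoptosis) and 0.0798 (integrated stress). That test does not compare a list with the other genes. Lists of other kinds passed it too, such as histone ubiquitination enzymes (0.0023), m6A machinery (0.0155) and epithelial markers (0.0023). Mitosis (0.413) and cytosolic ribosomal proteins (0.349) were among those that did not. Of 24 NF-kB and inflammatory genes, 7 rose, 2 fell and 15 did not pass (7 and 3 adjusted over the list alone; median log2 change 0.17, camera adjusted p = 0.302). IL1B, the inflammatory cytokine, rose from 22.9 ± 15.7 to 107 CPM, a log2 change of 2.24 that was 1.65 without scrambled replicate 1 and 3.18 without scrambled replicate 2, and ZC3H12A, a ribonuclease that limits inflammatory transcripts, rose from 20.1 to 54.5 CPM, while NFKB2 fell from 97.3 to 55.6 CPM. Of 31 interferon-stimulated genes, 5 rose, 4 fell and 22 did not pass (8 and 5 adjusted over the list alone). IFITM3 rose from 121 to 252 CPM and IFITM2 from 67.6 to 176 CPM, though their near-identical sequences make both values uncertain. The median (-0.18) and the mean (-0.02) of this list were negative and its camera test pointed up (adjusted p = 0.595). In the integrated stress and unfolded protein response, 5 of 32 rose and none fell (4 adjusted over the list alone; median 0.14, camera adjusted p = 0.173). The amino acid transporter gene SLC7A5 rose from 435 to 1030 CPM and DDIT4, an inhibitor of mTORC1, rose from 130 to 322 CPM. This list passed without knockdown replicate 1 (adjusted p = 0.00193) and without scrambled replicate 1 (0.000671), and the NF-kB list without knockdown replicate 2 (0.0187). Of 25 p53 target genes, 4 rose, 2 fell and 19 did not pass (8 and 5 adjusted over the list alone; median 0.15, camera adjusted p = 0.603). CDKN1A, the cell cycle inhibitor p21, rose from 103 to 178 CPM, and FBXW7, a substrate adaptor of a ubiquitin ligase, fell from 31.6 to 10.9 CPM. Of 31 apoptosis regulators, 5 rose, 1 fell and 25 did not pass, with 5 and 1 adjusted over the list alone (median 0.12, camera adjusted p = 0.298). MCL1 and CFLAR, both inhibitors of cell death, rose from 926 to 1656 CPM and from 52.1 to 96.0 CPM, while BCL2L2, another such inhibitor, fell from 101 to 45.9 CPM. Without 1 library, MCL1 lost its call in 4 of 4 fits (highest adjusted p 0.146), SLC7A5 in 3 (0.0943, kept without scrambled replicate 1), and CDKN1A (0.0982) and DDIT4 (0.111) without knockdown replicate 1 or scrambled replicate 2. CFLAR (0.0684) lost it without replicate 1 of either group and NFKB2 (0.0752) and BCL2L2 (0.0830) without knockdown replicate 1.

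Metabolic lists did not pass camera either in the fit without a block, though hypoxia and glycolysis passed it with the replicate block (adjusted p = 0.0449). Of 36 genes of hypoxia and glycolysis, 3 rose and 2 fell (1 and 2 adjusted over the list alone; median log2 change 0.27, camera adjusted p = 0.189), among them the glucose transporter gene SLC2A3 (log2 0.89) and the hexokinase gene HK1 (-0.83). Of 24 cholesterol synthesis genes, 3 rose and 1 fell, as also adjusted over the list alone (median 0.18, camera adjusted p = 0.343), with SC4MOL at 0.72 and CYP51A1 at -0.54. Of 54 nuclear-encoded oxidative phosphorylation genes, 4 rose and 3 fell, and 4 and 3 adjusted over the list alone (median 0.13, camera adjusted p = 0.302), with ATP5D at 0.91 and UQCRB at -0.98. Cytosolic ribosomal protein genes stayed close to the median of all genes. Of 73 tested, only RPL23A rose (log2 0.66, adjusted p = 0.0437), a gene with many pseudogenes, and none passed adjusted over the list alone (median 0.05, camera adjusted p = 0.744). Of 11 osteoblast genes, SPARC and COL1A1 rose (log2 1.09 and 2.08) and TNFRSF11B, which encodes osteoprotegerin, fell (-1.48). Adjusted over the list alone, 3 rose and 1 fell (median 0.02, camera adjusted p = 0.422). Single libraries decided several of these results: hypoxia and glycolysis passed upward without knockdown replicate 2 (adjusted p = 0.0188) and without scrambled replicate 1 (1.70e-06), cholesterol synthesis without knockdown replicate 1 (0.0152) and oxidative phosphorylation without scrambled replicate 1 (0.0390). CYP51A1 lost its call in each of the 4 fits with 1 library left out (highest adjusted p 0.197), HK1 (0.122) and TNFRSF11B (0.0694) in all but that without scrambled replicate 2, and RPL23A (0.248) and SC4MOL (0.127) in all but that without knockdown replicate 1. SLC2A3 (0.167) lost it without knockdown replicate 1 or scrambled replicate 2, SPARC (0.0658) without replicate 1 of either group, COL1A1 (0.0894) without either scrambled replicate, with its log2 change at 1.24 without knockdown replicate 1, and UQCRB (0.0592) without knockdown replicate 1.

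Markers of other cell types were mostly low. Of 9 epithelial markers, 2 rose, and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.459). KRT18, which was not low, rose from 554 ± 12.6 to 1041 ± 12.1 CPM (log2 0.91), and KRT7 from 1.34 ± 0.28 to 3.68 ± 0.421 CPM (log2 1.46). Both lost their calls when any 1 library was left out (highest adjusted p 0.0713 and 0.133). Of 6 endothelial markers none passed the edgeR test over all genes or adjusted over the list alone, and the smallest unadjusted p was 0.0962, with TIE1 at 264 ± 23.4 CPM after knockdown and 213 ± 27.5 CPM in the scrambled libraries. Their median log2 change was 0.003, their mean was -0.10 and their camera test pointed up (adjusted p = 0.963). Of 4 leukocyte markers tested, LCP1 alone rose, over all genes and adjusted over the list alone (median 0.75, camera adjusted p = 0.0246; adjusted p = 0.773 with an estimated correlation). That list did not pass without scrambled replicate 2 (adjusted p = 0.0893) or with low counts kept (0.219).

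**Figure D2:**
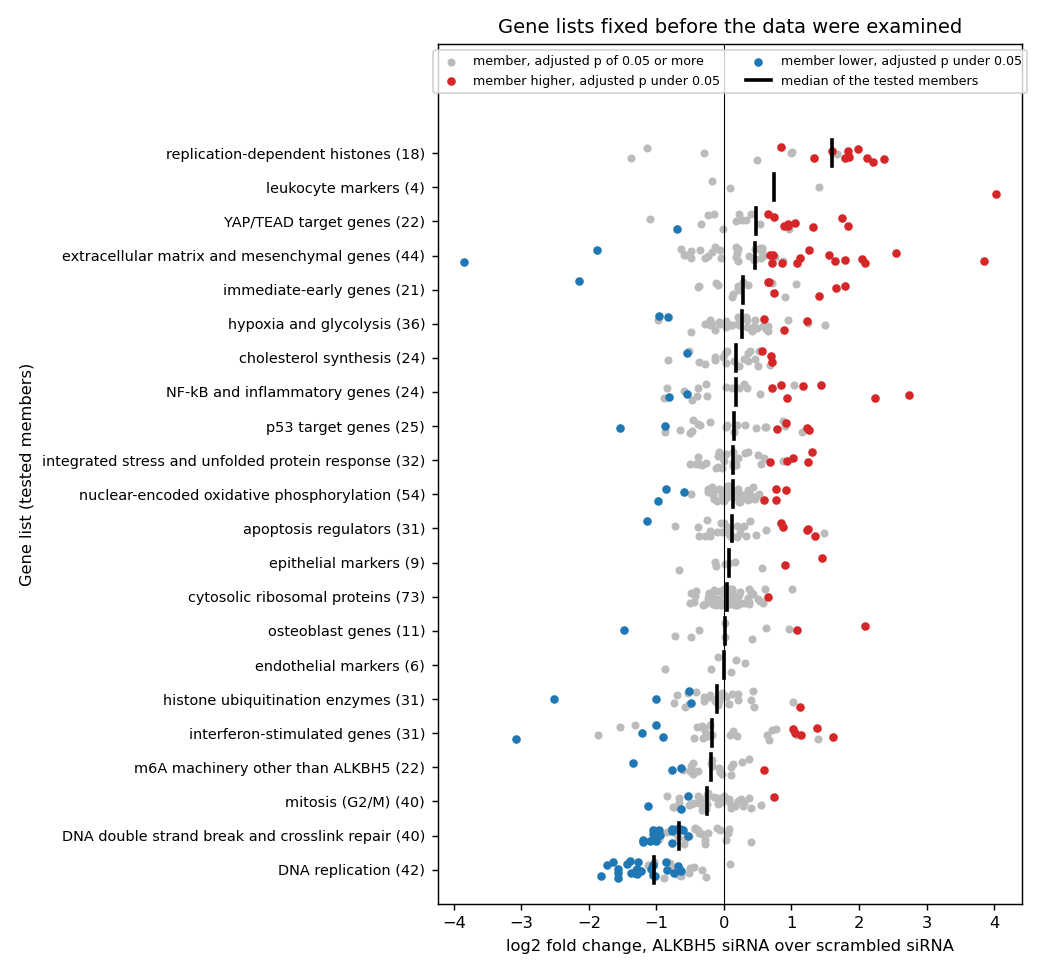
Log2 fold changes (ALKBH5 siRNA over scrambled siRNA, 2 libraries each) of the tested members of each gene list, with 1 point per gene coloured by whether it passed the threshold and a bar at the list median. DNA replication genes lie lowest, with a median of -1.04, and replication-dependent histones highest, with a median of 1.61.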

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

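No call turned in direction for any of the 1374 higher or 1384 lower genes under the other scalings, filters, tools, the block or with a library left out. Requiring a log2 change of at least 1 left 706 higher and 619 lower genes by construction. Without 1 library, higher genes ranged from 462 to 831 and lower genes from 379 to 792, in fits with fewer libraries, in which the lone library of a group is assumed to vary like the other group. Replicate numbers are shared between groups with no label saying what they share. Deviations of same-numbered libraries correlated at 0.325, and a fit with the replicate block called 2354 higher and 2357 lower genes, 100% of the calls without the block among them; of the lists fixed beforehand it changed the call of only hypoxia and glycolysis, which then passed (0.0449), and the 2 added lists were not run with it. The counts of the other settings lay within 1.5 times, from 1267 to 1799 higher and from 1240 to 1980 lower genes. With an estimated correlation the adjusted p was 0.773 for DNA replication, repair, YAP/TEAD, matrix, histone, immediate-early and leukocyte genes, and fry gave 0.149 for the first 4 and 0.106 for the last 3; only 2 residual degrees of freedom inform these tests. Immediate-early genes ranged from 0.00258 to 0.0634 with 1 library left out and leukocyte markers from 0.00121 to 0.0893, while keeping low counts gave 0.219 for leukocyte markers. Of lists that did not pass in the unblocked fit of all libraries, those that passed with some single library left out ranged from 0.0187 to 0.847 (NF-kB), 0.000671 to 0.893 (integrated stress), 1.70e-06 to 0.788 (hypoxia), 0.0152 to 0.721 (cholesterol) and 0.0390 to 0.841 (oxidative phosphorylation). The mitosis list ranged from 5.69e-07 to 0.698, and turned upward at 0.0188 without scrambled replicate 1; the cause was not tested. Of 96 genes that passed and were eligible by the rule for named genes, 38 and 33 lost their call without knockdown replicates 1 and 2, and 33 and 25 without scrambled replicates 1 and 2. Depth and 2 libraries per group limit calls at small folds. The simulation recovered 1.49% of changes at 1.5-fold, but it changed far fewer genes than were called here, so that rate does not carry over.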

Other observations

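The actin and contractile targets of SRF and its cofactor MRTF rose as a group. The list was written after the rises of TAGLN and other actin genes had been seen, and is not independent of them. Of 30 genes tested, 21 rose, none fell and 9 did not pass (22 and 2 adjusted over the list alone), with a median 2.01-fold higher. FLNA, which encodes filamin A, rose from 2279 ± 8.91 to 7567 ± 826 CPM, MYL9, a myosin light chain, from 32.7 ± 1.8 to 189 ± 56.7 CPM, VCL, which encodes vinculin, from 730 ± 56.8 to 1483 ± 23.1 CPM and LIMA1 from 94.6 ± 4.37 to 309 ± 8.71 CPM. SRF itself was at 173 ± 23.7 CPM against 118 ± 21.5 CPM (adjusted p = 0.0649), and ANKRD1 and CTGF had log2 changes of -1.10 and -0.33 without passing, though ANKRD1 passed at -2.09 without knockdown replicate 2 (adjusted p = 0.0234). VCL lost its call without knockdown replicates 1 and 2 (adjusted p = 0.0621 and 0.0603) and without scrambled replicate 1 (0.0766). Over the 2 added lists, the group had an adjusted p = 0.0261 with an estimated correlation and of 0.0043 by fry.

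Mitochondrial ribosomal protein genes, the other added list, were lower in part. Of 75 tested, 11 fell, 1 rose and 63 did not pass, with the same numbers adjusted over the list alone. Of the 17 members with GAGATGG in the 3′ UTR 6 fell (median log2 change -0.37, SE 0.14), and of the 57 without it 5 fell (median -0.10, SE 0.06). These SEs came from resampling genes as if independent. MRPS27 fell from 334 ± 30.2 to 69.1 ± 9.60 CPM and MRPS9 from 58.4 ± 7.06 to 10.9 ± 1.93 CPM, while MRPL34 rose from 37.0 ± 5.90 to 57.3 ± 0.416 CPM but lost its call without knockdown replicates 1 and 2 (adjusted p = 0.136 and 0.134) and without scrambled replicate 1 (0.175). The median log2 change was -0.15 (camera adjusted p = 0.00445; adjusted p = 0.313 with an estimated correlation).

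In the tests below, the 7-mers were found by scanning the same fold changes, and the tests of length and GC content, of Alu elements in either orientation and of dividing cells, and the removal of coding length and GC content from coding sites, were chosen after the result was seen. The scores, permutations and SEs of shifts treat genes as independent and do not measure the spread between libraries. Of all 16379 7-mers, GAGATGG had the lowest score in 3′ UTRs (z = -13.6, where the lowest of 100 permutations was -4.73). A candidate explanation is repression through the seed of an ALKBH5 siRNA, whose sequence is not given in the sources used here. ALKBH5 itself held the 7-mer in 3 of 3 transcripts, which this explanation needs. The 7-mer is common, however. Of the 10331 compared genes, 2177 held it in the 3′ UTR and 1856 in the coding sequence alone, so its presence in ALKBH5 weighs little. Genes with a site and no Alu-like GAGATGGGG shifted by -0.242 (log2, SE 0.018), genes with the reverse complement by 0.004 (SE 0.018) and genes with coding sites alone by -0.160 (SE 0.016). As full accounts of this shift, Alu elements (-0.265 in 3′ UTRs without any Alu-like 10-mer, SE 0.024) and length or GC content (-0.226 once removed, SE 0.016) were argued against. Alu-like 3′ UTRs without the 7-mer shifted by -0.0535 (SE 0.0168) against 3′ UTRs with neither. A smaller shift thus went with Alu-like sequence itself, though the median log2 changes were 0.0048 and 0.0066. A loss of ALKBH5 came with the same transfection and stays open. Genes with the methylation motif GGACT in the 3′ UTR shifted by -0.0017 (SE 0.0125), so they were not lower as a set. The motif stood in 6820 of the compared genes and was absent from 3511. It is too common to single out methylated transcripts, so this test cannot decide on an effect through methylation.

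The genes the study followed may carry part of this shift. USP22, with a log2 change of -2.52, held 5 sites in its 3′ UTR. The 35 other compared genes with at least 5 shifted by a mean of -0.268 (SE 0.093), with a median log2 change of -0.11, no further than genes with 2 sites (-0.302). The usual shift with such sites was thus far smaller than the fall of USP22. RNF40, with a log2 change of -0.51, held none in its 3′ UTR and 4 in its coding sequence. The 29 other genes with at least 4 coding sites and none in the 3′ UTR shifted by -0.326 (SE 0.12), with a median of -0.14. Both hold sites for such a seed, as do many of the compared genes, so this alone says little about either. An effect of ALKBH5 itself on either gene was not tested. On the control side, genes with GAATATA in the 3′ UTR were higher by 0.126 (SE 0.0167), with the reverse complement at -0.009 (SE 0.02), which may reflect a seed of the scrambled siRNA; AT-rich sequence was argued against, as 105 7-mers of the same composition had a median z of 0.323.

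The fall of DNA replication genes was weighed against sites and against fewer dividing cells. Members without GAGATGG in the 3′ UTR had a median of -1.042 (SE 0.107), which argues against 3′ UTR sites as the cause. Members with coding sites, such as RRM1 with 1, were kept among them, so coding sites were not tested. A uniform loss of dividing cells would lower mitotic genes alike, and the mitosis median lay 0.795 above that of replication, by 0.659 to 0.957 in the 4 pairings of a knockdown with a scrambled library. The genes of each list move together (estimated correlation 0.716 for replication and 0.837 for mitosis). The SE of 0.107 came from resampling members as if independent, so it understates the uncertainty. Over those pairings the mitosis median went from -0.62 to 0.38 and the replication median from -1.38 to -0.54. A block before DNA synthesis or an indirect effect of either siRNA may remain, and neither was tested beyond these values.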
